A study of Drosophila melanogaster with 2 samples.

How the data were processed

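Chromatin immunoprecipitation and sequencing was done on whole embryos aged 0 to 24 h that carry an eGFP-tagged stc, per the labels, with chromatin sheared by sonication to 200 to 800 bp. There were 2 biological replicates of 1 group, taken from the replicate numbers in the labels. The labels name a possible control experiment, which was not analysed here, so no background could be measured in control samples.

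The deposited files analysed here are lists of peaks on the dm6 build, per the labels. The aligner and the peak caller are not given in the sources used here. For each replicate there was a list of ranked peaks and a thresholded list, and for the series 2 ranked and 2 thresholded lists, of which the conservative thresholded list was the main list. Its peaks all occur in the ranked list whose inputs were the 2 replicates: 72.4% of that list's peaks had the exact coordinates of a replicate 1 ranked peak as their first input and 81.6% those of a replicate 2 ranked peak as their second. The inputs of the other ranked list matched neither replicate. The signal of a peak was deposited as the authors' peak caller gave it, with its scaling not given in the sources used here. The score is the deposited measure of the irreproducible discovery rate (IDR), which compares the ranks of peaks in a pair of lists. The −log10 values of the q-value and of the IDR were deposited by the authors beside each ranked peak. Every peak of the thresholded lists had an IDR of 0.01 or less, tested on the files, so that the stricter threshold of 0.01 planned as an alternative removed no peak.

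Gene positions came from the Ensembl annotation BDGP6.54, release 115, and sequence from the RefSeq Release 6 assembly, the assembly of which dm6 is the browser name. All peak ends lay within the chromosome lengths of that reference. Peaks on 2L, 2R, 3L, 3R, 4 and X were used. Positions in the text count from 1. A gene was bound when a summit lay within 250 bp of any of its TSSs, and its position was taken from the nearest of them, for the peak of highest signal. Each summit was given to a class in the order promoter, 5' UTR, coding exon, 3' UTR, intron, other exon and intergenic. Peaks were shared when they overlapped by at least 50% of the shorter peak, and the overlap was set against 1000 random placements. Shares carry exact (Clopper-Pearson) 95% confidence intervals, which cover counting error only. Odds ratios carry Woolf intervals, and those stratified carry Mantel-Haenszel intervals. The p values of stratified tests came from a normal approximation. For a count of 0, the share that it allows is the upper limit of the exact interval.

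The tests were an exact binomial test for location, Fisher's exact test for gene lists, chromosomes, promoter motifs and head-to-head genes, the exact McNemar test for motifs and words of 6 bases within 50 bp of the summit against a window centred 300 bp away on a randomly drawn side, and a permutation test of the median log10 signal with 100000 permutations. All were two-sided, except the comparison with random placements, and p values were adjusted by the Benjamini-Hochberg method within each family. Peaks and genes are the units of these tests, not embryos, so the p values do not measure the spread between replicates. Promoter motifs were searched from 150 bp upstream to 50 bp downstream of the TSS farthest 5'. Motifs and words were searched on both strands, at promoters and at summits. Genes were head to head when a TSS of another gene on the opposite strand lay upstream within 500 bp. Non-coding and histone lists were compared with all genes, the others with protein-coding genes.

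The 29 gene lists, the 20 motifs, the tests and the rule for naming genes were fixed before the data were examined. The rule named stc, the 25 promoter peaks of highest signal that overlap a peak of each replicate's own list, each by the protein-coding gene with the nearest TSS, and up to 4 bound members of highest signal in each list. Of 396 symbols in lists given by symbol, 380 matched the annotation. CP190 of the chromatin list did not match, because the annotation writes it Cp190, and that gene was taken into the chorion list by its name pattern. The lists were kept as fixed, and the function of each member was not checked.

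The tests were run on 20 simulated peak lists with known answers. For the gene lists, over 13945 protein-coding genes, 40 of 40 planted lists were called and 6 of 540 lists without planted peaks were called as bound more often. The planted gene lists were the cytoplasmic ribosomal proteins and axon guidance, at shares near those observed, so smaller effects were not covered. False calls of lists as bound less often were not counted. Promoter peaks were planted only at protein-coding genes. The simulations therefore do not cover the calls of lists bound less often. For the motifs at summits, the planted motif was called in 20 of 20 lists, and 3 of 360 tests of other motifs gave a call. The simulated summits lay at random positions, so these motif counts do not cover the lower GC content of the real summits.

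The alternatives were other overlap rules, the larger thresholded list, each replicate's own list in place of the joint one, TSS distances of 100 and 500 bp, a background of genes with a ranked peak, other motif windows, an IDR threshold of 0.001, a threshold of 0.05 on the ranked list with no region excluded, a list without peaks that overlap a stronger one, shuffled windows and stratified tests. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.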

Results

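Binding of the shuttle craft protein (stc), a zinc finger protein related to human NFX1, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos collected from 0 to 24 h. The protein carried an enhanced green fluorescent protein (eGFP) tag and was pulled down with an antibody against GFP. The DNA recovered can include DNA that the tagged protein, or anything crosslinked to it, contacted, and background DNA as well. No control experiment was analysed here, so a peak at a gene called bound may also reflect background. There was 1 group with 2 biological replicates and no comparison between conditions. Each measurement is a peak, an interval of the genome where the authors called an excess of reads, with a summit and a signal value. Replicate 1 had 2782 peaks and replicate 2 had 3806 in their own thresholded lists. The list kept between the replicates, on which the results below rest unless another list is named, had 3831 peaks with a median width of 350 bp. Read depth was not given in the files, so the depth behind a peak is unknown. The signal is the authors' value for a peak and is used only to describe or rank peaks.

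Peaks were shared between the replicates far more often than random placement gave. Replicate 2 had the larger number of peaks not found in the other. Of the 2767 replicate 1 peaks on the main chromosomes, 2063 (74.6%, exact 95% confidence interval 72.9 to 76.2) overlapped a replicate 2 peak. Of the 3806 replicate 2 peaks, 2059 (54.1%, 52.5 to 55.7) overlapped a replicate 1 peak. Random placement of the same peaks within their chromosomes gave 0.910% and 0.657% on average, with highest values of 1.55% and 1.18% among 1000 placements (permutation p = 9.99e-04 in each direction, one-sided, the smallest the placements can give). The placements were uniform along each chromosome and did not allow for regions that may give peaks in any library. This comparison therefore cannot tell shared binding from shared background. Shared replicate 1 peaks had a median signal of 90.2 and unshared ones 52.6. Of the 3831 peaks kept between the replicates, 2037 (53.2%) overlapped a peak in both replicates' own lists, 375 in replicate 1 alone, 721 in replicate 2 alone and 698 in neither. Across the 2037 peaks found in both, Spearman's rho between the replicates' signals was 0.782, a correlation across peaks, which are not independent replicates.

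**Figure D1:**
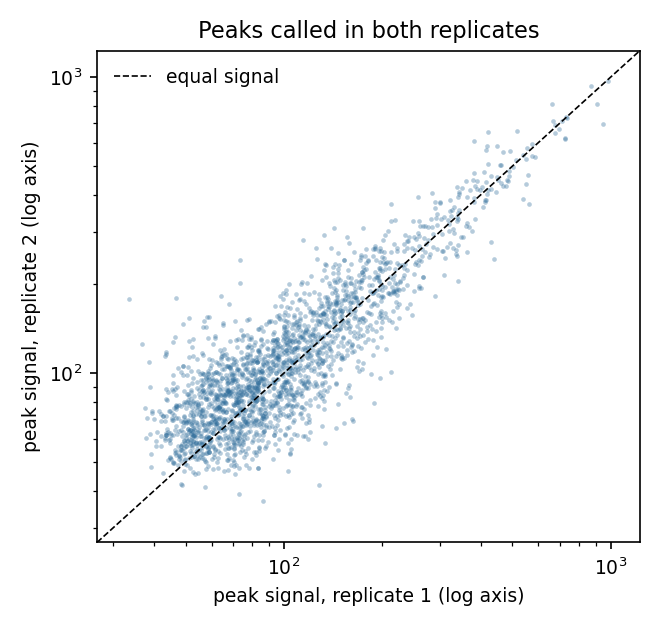
Peak signal in replicate 1 (horizontal, log axis) against replicate 2 (vertical, log axis) for the 2037 peaks called in both replicates' own lists. Each point is a peak, the dashed line marks equal signal, and Spearman's rho across peaks is 0.782.

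The first question is where in the genome the peaks lay. Promoters and introns held most summits, and coding sequence held almost none. Of the 3831 summits, 1269 (33.1%, exact 95% confidence interval 31.6 to 34.6) lay within 250 bp of a transcription start site (TSS), a region that covers 7.49% of the bases, a ratio of 4.42 (exact binomial test, two-sided, log10 p = -460.1). By the same exact test, adjusted over the classes, introns held 1727 summits (45.1% against 41.2% of the bases, adjusted p = 1.38e-06) and intergenic sequence 663 (17.3% against 28.5%, adjusted p = 3.32e-58). Coding exons held 29 (0.757% against 15.6%, exact test, adjusted p = 1.26e-229) and 3' UTRs 39 (1.02% against 4.76%, adjusted p = 1.29e-38). Other exons, those of non-coding transcripts or outside the annotated coding and untranslated parts, held 67 (1.75% against 1.19%, exact test, adjusted p = 0.00318). The 37 summits in 5' UTRs beyond the promoter window did not differ from the share of the bases (0.966% against 1.33%, exact test, adjusted p = 0.0560). Ranked peaks of the same libraries that failed the threshold lay near a TSS in 10.5% of 104287 cases (odds ratio 4.22, 95% confidence interval 3.93 to 4.52, Fisher's exact test, two-sided, p = 4.41e-295).

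**Figure D2:**
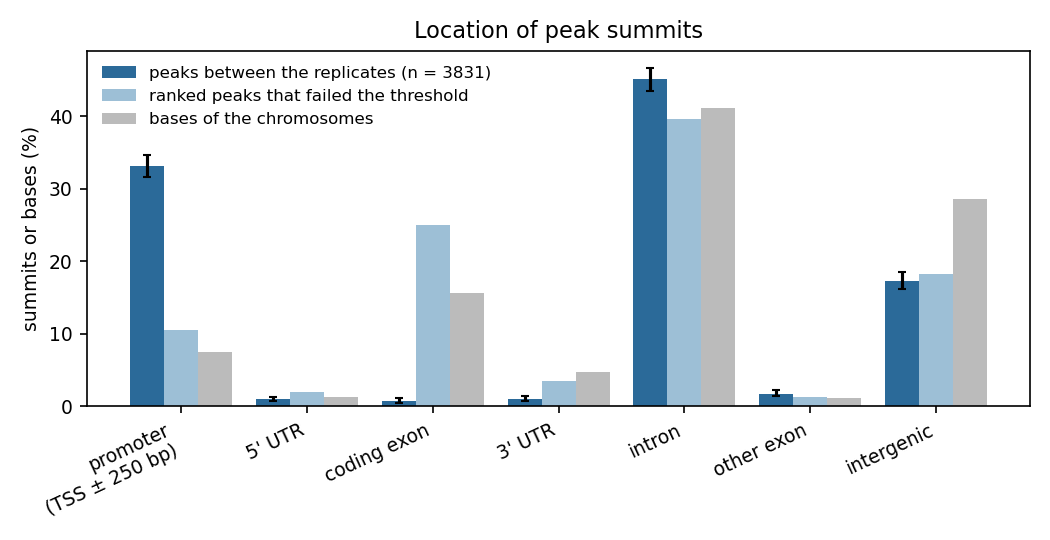
Share of summits (%) in each class of annotation for the 3831 peaks kept between the replicates, for ranked peaks that failed the threshold, and the share of bases in each class. Error bars are exact 95% confidence intervals; promoters hold 33.1% of the kept peaks, 10.5% of the failed peaks and 7.49% of the bases.

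At promoters most summits lay just upstream of the start site. A summit lay within 250 bp of a TSS at 1429 of 13945 protein-coding genes (10.2%), from 1105 peaks, since a peak between neighbouring genes counts for both. The summit was upstream of the TSS nearest to it at 1173 of these genes (82.1%, exact 95% confidence interval 80 to 84.0, exact binomial test against 50%, two-sided, p = 2.63e-140), with a median position of -115 bp and an interquartile range of -163 to -44 bp. A peak between a head-to-head pair can be upstream of both genes and then counts for each, so that the genes are not independent. This by itself raises the upstream share above 50%. The share was not computed per peak, so the size of this effect is unknown.

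**Figure D3:**
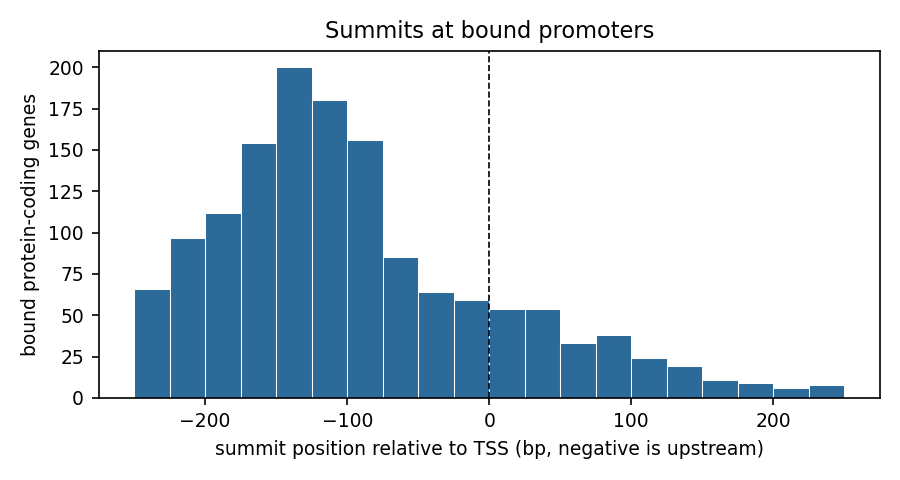
Position of the summit relative to the TSS (bp, negative values upstream) at the 1429 bound protein-coding genes, in bins of equal width. Bars give the number of genes; the dashed line is the TSS and the median position is -115 bp.

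The strongest promoter peak lay at Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, on chromosome X from 2703728 to 2704042 (dm6). Its summit was 21 bp upstream of the TSS, its signal was 1950.8, the highest of the list, and it ranked 1 in each replicate. The peak at mRpL41 (FBgn0034001), a mitochondrial ribosomal protein gene, spanned 15217602 to 15217903 on 2R, with a signal of 1629.4. At Art3 (FBgn0038306), an arginine methyltransferase gene that lies head to head with the mitochondrial ribosomal protein gene mRpS10, the peak spanned 15229395 to 15229673 on 3R, with a signal of 1364.9. PNPase (FBgn0039846), the mitochondrial polynucleotide phosphorylase, had a peak from 31404520 to 31404793 on 3R with a signal of 1361.0. Chro (FBgn0044324), the chromatin and spindle matrix protein Chromator, had a peak from 22878751 to 22879061 on 3L with a signal of 1349.8. The peak at eIF6 (FBgn0034915), a factor of ribosome assembly and translation initiation, spanned 23850264 to 23850544 on 2R with a signal of 1123.1. Gapdh2 (FBgn0001092), a glycolytic enzyme gene, had a peak from 15867839 to 15868121 on X with a signal of 992.2.

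Of the 25 strongest promoter peaks found in both replicates, 21 had the summit upstream of the nearest TSS, at distances of 21 to 204 bp, and signals ran from 957.3 to 1950.8. The others with a named gene were CenG1A, Fkbp14, Tcs5, px, Tina-1, gish, RluA-1, osp, MFS18, mRpL23 and tank, and 7 carried a CG number as their name (CG14100, CG18549, CG7601, CG5611, CG13390, CG8320 and CG1635). Among the 25, 13 genes had a head-to-head neighbour. Each peak ranked 66 or better in each replicate's own list.

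Ribosomal protein genes were bound more often than any other list tested. Of the 93 genes for cytoplasmic ribosomal proteins, the structural proteins of the cytosolic ribosome, 57 were bound (61.3%, exact 95% confidence interval 50.6 to 71.2), against 9.90% of other protein-coding genes (odds ratio 14.4, 95% confidence interval 9.45 to 21.9, Fisher's exact test, two-sided, adjusted p = 8.18e-32 over 29 lists). The strongest were RpL32 (signal 401.9), RpS27 (362), RpL34b (340) and RpL14 (337.5). The RpL32 peak lay at 30046129 to 30046434 on 3R, 120 bp upstream of the TSS. Signals of the 57 had a median of 167, under those of the strongest promoter peaks, and the median summit position was -13 bp. The peak overlapped one in both replicates' own lists at 44 of the 57 genes. In the replicates' own lists 52 and 55 of the 93 genes were bound.

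Axon guidance genes, which steer growing nerve fibres, were bound more often in the list kept between the replicates, a call that was not made in replicate 1. Of 50 genes, 14 were bound (28.0%, 16.2 to 42.5) against 10.2% of the others (odds ratio 3.43, 1.85 to 6.38, Fisher's exact test, adjusted p = 0.00172). The strongest members of the list as fixed were fray (signal 285.6), trio (241), PlexA (236), a semaphorin receptor gene, and Ten-a (160.9). Membership was by symbol, and a role in axon guidance was not checked for each gene, fray included. The PlexA peak spanned 1027219 to 1027377 on chromosome 4. The signal of the 14 had a median of 114.8, and the peak overlapped one in both replicates' own lists at 4 of them, in 1 replicate at 7 and in neither at 3. Replicate 2's own list had 19 of the 50 genes (odds ratio 5.14, adjusted p = 3.96e-06) and replicate 1's 6 (odds ratio 1.53, adjusted p = 0.541, Fisher's exact test). At a threshold of 0.001 on the irreproducible discovery rate (IDR) of the peaks the odds ratio was 2.39 (Fisher's exact test, adjusted p = 0.161).

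Of the lists for general cell functions, none beyond the cytoplasmic ribosomal proteins passed the test. Mitochondrial ribosomal protein genes were bound at 10 of 73 (13.7%, 6.77 to 23.8, Fisher's exact test, adjusted p = 0.532), with mRpL41 (signal 1629.4), mRpS10 (1364.9), mRpL23 (993.2) and mRpS2 (609) the strongest. Translation factor genes were bound at 9 of 54 (16.7%, 7.92 to 29.3, Fisher's exact test, adjusted p = 0.324), among them eIF6 (1123.1), eEF1gamma (365.1), eIF5B (222.3) and eEF1alpha1 (162.7). Translation factors passed the test in replicate 2's own list, with 12 of 54 bound (odds ratio 2.38, Fisher's exact test, adjusted p = 0.0470), in the larger thresholded list of the series (odds ratio 2.51, adjusted p = 0.0176) and at 100 bp from the TSS (odds ratio 3.41, adjusted p = 0.0420). Proteasome genes were bound at 2 of 48, Rpn3 (161.7) and Prosbeta2 (128.8), and oxidative phosphorylation genes at 5 of 86, with ND-MWFE (252) and ND-24 (225.5) the strongest (Fisher's exact test, adjusted p = 0.418 and 0.410). Splicing factors were bound at 3 of 26, heat shock and chaperone genes at 5 of 27, with Hsp27 (674.6) and Hsp83 (436.2) the strongest, replication and cell cycle genes at 6 of 36, with Dp (294.5) and RnrS (221.3), ubiquitin pathway genes at 4 of 33, and genes of mRNA decay and translation control at 4 of 27, with orb (399.7) and Smg5 (267.6). Adjusted p in Fisher's exact test lay between 0.394 and 0.972 for these lists. Chromatin and Polycomb regulators were bound at 7 of 41 (17.1%, 7.15 to 32.1, Fisher's exact test, adjusted p = 0.394), with Chro (1349.8), brm (706.9), the ATPase of a chromatin remodelling complex, E(z) (409.4), the Polycomb histone methyltransferase, and Trl (294.1) the strongest.

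The following lists of tissue and patterning genes did not pass the test either. The gut and salivary gland list, as fixed, had 4 of 19 genes bound (tin, fkh, CrebA and grn, signals 501.5 to 86.57). Segmentation genes were bound at 3 of 24 (nkd, cad and bcd, 420.1 to 82.67), neuronal fate regulators at 3 of 34 (numb, da and vvl, 349.1 to 101.7) and muscle genes at 2 of 26 (sls and Mef2). Glial genes were bound at 1 of 11 (moody, 418), haemocyte and fat body genes at 1 of 17 (ush, 80.87), and the chorion and vitelline list at 1 of 19, where the bound member, Cp190, encodes an insulator protein that the name pattern of the list took in. Adjusted p in Fisher's exact test lay between 0.324 and 1 for these lists. No gene was bound among 8 Hox genes, 28 pan-neuronal genes, 37 testis genes and 22 gut proteases. By the exact intervals these lists could have shares of up to 36.9%, 12.3%, 9.49% and 15.4%. Their adjusted p values in Fisher's exact test were 1, 0.324, 0.105 and 0.387. The testis genes passed the exact test in the larger list (adjusted p = 0.0261), in the ranked list at an IDR of 0.05 with no region excluded (0.0164) and at 500 bp from the TSS (0.0428).

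Cuticle, chemoreceptor, histone, snoRNA and tRNA genes were bound less often than other genes. No member was bound among 120 cuticle protein genes (up to 3.03% by the exact interval, Fisher's exact test, adjusted p = 3.59e-05). None was bound among 231 chemoreceptor and odorant-binding genes (up to 1.58%, Fisher's exact test, adjusted p = 2.55e-10) or 111 histone genes (up to 3.27%, adjusted p = 5.75e-04). The histone genes are repeats of near-identical copies, so that their count of 0 is uncertain, since how reads of repeats were placed is not given in the sources used here. Their call ended at 100 bp from the TSS (Fisher's exact test, adjusted p = 0.144) and against genes with a ranked peak (adjusted p = 1). No histone gene was bound in either setting. Of 269 snoRNA genes 2 were bound (0.743%, adjusted p = 2.55e-07), and of 290 tRNA genes 11 (3.79%, 1.91 to 6.68, odds ratio 0.423, Fisher's exact test, adjusted p = 0.0110), the strongest at tRNA:Tyr-GTA-1-8 (585.3). The tRNA result depended on the replicate and the list. Replicate 1's own list had 2 bound tRNA genes (odds ratio 0.0967) and replicate 2's had 41 (odds ratio 1.66, Fisher's exact test, adjusted p = 0.0212). The call also ended in the larger list (odds ratio 1.02, Fisher's exact test, adjusted p = 0.994) and at 100 bp from the TSS (odds ratio 0.388, adjusted p = 0.182). Of 32 snRNA genes 2 were bound, snRNA:U1:95Ca (152.6) and snRNA:U5:63BC (130.7), with an adjusted p of 1. Within strata of TSS number and head-to-head status the calls for cuticle, tRNA and snoRNA genes ended, with odds ratios of 0.627 (0.337 to 1.17) for tRNA and 0.186 (0.0462 to 0.747) for snoRNA genes, and no bound cuticle gene in any stratum. The stratified p values came from a normal approximation in place of Fisher's exact test, which is uncertain at such low counts. Whether the strata or the change of test ended these calls cannot be told. The unadjusted snoRNA interval stayed under 1.

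**Figure D4:**
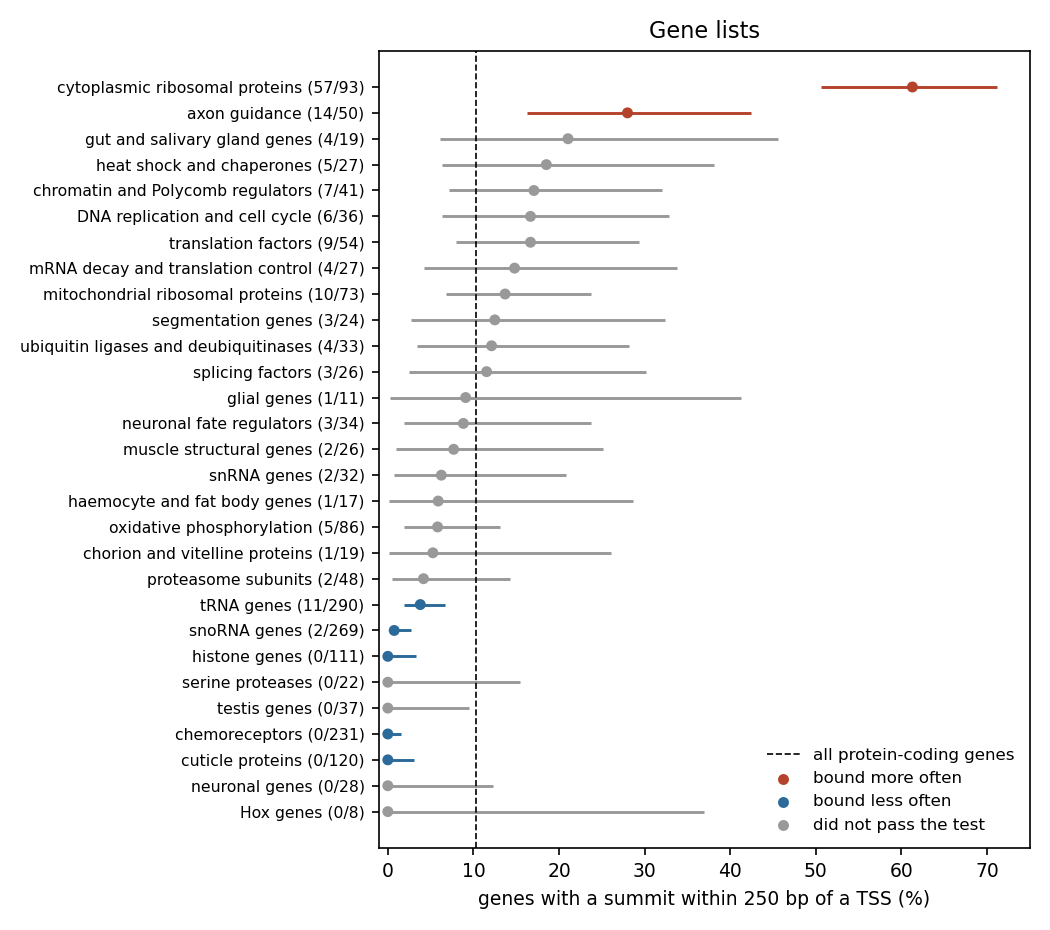
Percent of genes with a summit within 250 bp of a TSS in each of the 29 lists, with the counts bound and tested in parentheses. Points are shares, lines exact 95% confidence intervals and the dashed line the 10.2% of all protein-coding genes; cytoplasmic ribosomal proteins reach 61.3%.

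Promoters on the X chromosome were bound less often than those on the autosomes. On X, 170 of 2196 protein-coding genes were bound (7.74%) against 10.7% elsewhere (odds ratio 0.699, 0.592 to 0.826, Fisher's exact test, adjusted p = 1.02e-04 over 6 chromosomes). Away from promoters the density of peaks on X was 22.9 per Mb, against 16.5 on 3R and 21.2 on 3L. Chromosome 4 had 2 bound genes of 80 (odds ratio 0.224, Fisher's exact test, adjusted p = 0.0462). The odds ratio was 0.795 in replicate 2's own list (Fisher's exact test, adjusted p = 0.760). The call also ended, with odds ratios of 0.140 to 0.373, in replicate 1's own list (Fisher's exact test, adjusted p = 0.129), at an IDR of 0.001 (0.368), at 100 bp from the TSS (0.102) and without overlapping peaks (0.0680). Chromosomes 2L, 2R, 3L and 3R did not pass the test, with shares of 11.2%, 10.1%, 11.3% and 10.6%. In other settings some of them passed as bound more often. In the larger list, chromosome 2L (odds ratio 1.16, Fisher's exact test, adjusted p = 0.0294) and chromosome 3L (1.21, adjusted p = 0.00640) did so, as they did in replicate 2's own list (1.22 and 1.20, Fisher's exact test, adjusted p = 0.00925 and 0.0146). At 100 bp from the TSS chromosome 2L passed (1.32, Fisher's exact test, adjusted p = 0.0186), and in the ranked list at an IDR of 0.05 with no region excluded chromosome 3R did (1.14, adjusted p = 0.0309).

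Bound genes lay head to head with a neighbour more often than unbound ones. A TSS of another gene on the opposite strand lay within 500 bp upstream for 790 of 1429 bound genes (55.3%) and for 3344 of 12516 unbound genes (26.7%; odds ratio 3.39, 3.03 to 3.79, Fisher's exact test, two-sided, p = 1.80e-101). A peak between a head-to-head pair counts for both genes, which by itself raises this odds ratio. The exact test treats the genes of a pair as independent. No test counted each pair a single time, so the size of this effect is unknown.

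Promoter peaks had a slightly higher signal than other peaks, with a median of 139.5 against 120.9 (difference of 0.0622 on the log10 scale, permutation test, two-sided, p = 1.00e-05, the smallest that 100000 permutations can give). The share of promoter peaks was 51.3% in the tenth of peaks with the highest signal, 26.6% in the tenth ranked 8 by signal, the lowest share of any, and 34.5% in the tenth with the lowest signal. The sign of the difference turned when a promoter was a summit within 100 bp of a TSS (-0.0366, permutation p = 0.00858), and replicate 2's own list gave -0.00315 (permutation p = 0.820). In the larger list the difference was 0.0103 (permutation p = 0.242).

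Bound promoters differed from unbound ones in the motifs they held. A match counted on either strand and anywhere in the window searched. A TATA box, initiator or TCT match therefore need not be a working core element. The window lay at the TSS farthest 5', and the summit of a bound gene may lie at another of its TSSs. Motif 7, an element of housekeeping promoters, was present in 24.8% of bound and 14.7% of unbound promoters (odds ratio 1.91, 1.68 to 2.18, Fisher's exact test, adjusted p = 1.20e-19 over 20 motifs). By the same exact test the CAGCTG E-box was present in 20.5% against 13.4% (odds ratio 1.66, adjusted p = 2.90e-11), motif 1, the M1BP site, in 9.94% against 6.70% (1.54, adjusted p = 4.95e-05), the pyrimidine initiator TCT in 20.7% against 15.5% (1.42, adjusted p = 3.47e-06) and the DRE, the Dref site, in 10.5% against 7.96% (1.36, adjusted p = 0.00382). The BEAF core, motif 6, GAGA and ETS sites were also more frequent (odds ratios 1.18, 1.32, 1.44 and 2.60). The TATA box was less frequent in bound promoters (7.07% against 11.9%, odds ratio 0.565, Fisher's exact test, adjusted p = 7.85e-08), as were the initiator (21.1% against 30.1%, 0.621, adjusted p = 3.54e-12) and the Pho site (5.25% against 7.34%, 0.699, adjusted p = 0.00540). At an IDR of 0.001, where 2020 peaks remain, 5 of the 12 calls were made, and those for motif 1, the DRE, the BEAF core, motif 6, GAGA, ETS and Pho ended. Those for motif 6, GAGA and ETS also ended in replicate 1's own list, and that for ETS in replicate 2's, the larger list and the ranked list at an IDR of 0.05 with no region excluded. The X1 box, the element that gave mammalian NFX1 its name, was found in 0 of 1429 bound and 3 of 12516 unbound promoters. So rare a word could not show a difference between them (odds ratio 1.25, 0.0646 to 24.2). All these motif tests treat genes as independent, although a head-to-head pair can share sequence in the window searched. Head-to-head genes made up 55.3% of bound and 26.7% of unbound genes. No motif test was stratified by that status, so its part in these differences is unknown.

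At the summits themselves the sequence was rich in A and T. Mean GC content was 33.8% ± 10.4 (SD, n = 3831 peaks) in the 101 bp at the summit and 43.4% ± 9.89 in a window 300 bp away, a difference of -9.65 percentage points (SE 0.248). Of 2080 words of 6 bases, 415 were more frequent at summits and 916 less frequent (exact McNemar test, adjusted over all words), and 389 of the 415 held at most 2 G or C bases. Against shuffled summit sequence of the same dinucleotide composition, 176 words were more frequent and 187 less frequent. AAATAT was present at 33.9% of summits and 15.2% of control windows. Of the 20 fixed motifs, motif 6 (3.84% against 2.40%, exact McNemar test, adjusted p = 0.00127), the TATA box (4.23% against 2.48%, adjusted p = 1.40e-04) and runs of A (8.59% against 5.87%, adjusted p = 3.91e-05) were more frequent at summits, and the CAGCTG and CACGTG E-boxes, GAGA, TCT and CTCF elements less frequent. Against the shuffled sequence the CAGCTG, GAGA, TCT and CTCF elements were more frequent and the TATA box less frequent.

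**Figure D5:**
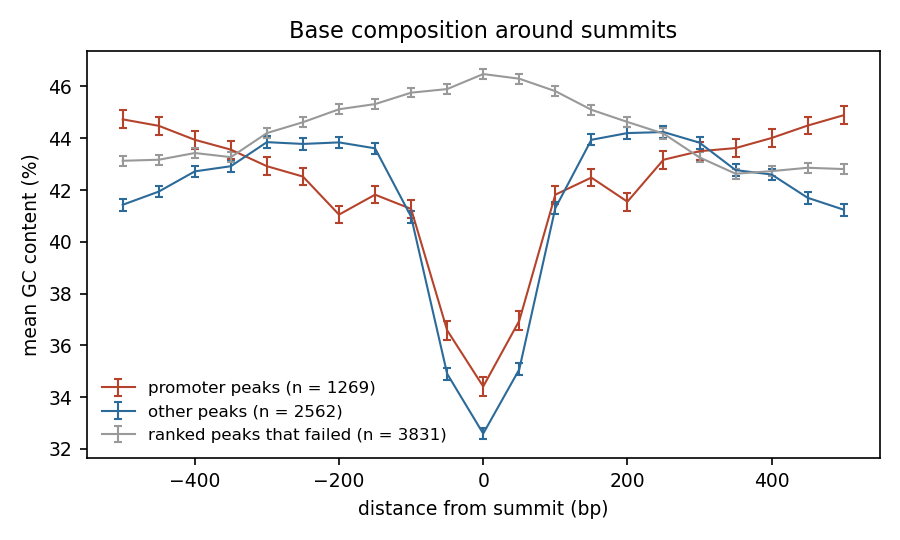
Mean GC content (%) in windows of 50 bp by distance from the summit (bp) for 1269 promoter peaks, 2562 other peaks and a random draw of 3831 ranked peaks that failed the threshold. Error bars are standard errors; GC falls to 34.4% at the summit of promoter peaks and 32.6% at that of other peaks, and is 46.5% at the summit of failed peaks.

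At its own gene, stc (FBgn0001978, 2L, 15113480 to 15118069, plus strand), the protein had no peak within 20 kb in the list kept between the replicates or in replicate 1's own list. Replicate 2's own list had a peak from 15113223 to 15113552 with its summit 92 bp upstream of the TSS and a signal of 86.6. The larger thresholded list of the series had 2 peaks, from 15113173 to 15113522 (signal 92.73), at the promoter, and from 15113975 to 15114324 (signal 53.64), with its summit 670 bp downstream of the TSS. The tag is in a transgene, so reads at this gene can come from the inserted copy as well.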

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

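Peaks outside the lists analysed were present in the ranked lists and on unplaced contigs. Between the replicates, 96 peaks passed an IDR of 0.01 in the ranked list but are not in the thresholded list, 56 of them on 3R and 29 on 2L. Their median signal was 126.5, against 126.2 for the peaks of the list, and 29 of the 95 on the main chromosomes (30.5%) lay within 250 bp of a TSS. The strongest, chosen after their values were seen, lay 1396 bp upstream of the nearest protein-coding TSS, that of cbt (480931 to 481255 on 2L, inside the annotated ush gene, signal 1703.5), and 963 bp upstream of that of Lk6 (11760913 to 11761185 on 3R, signal 1156.8). With those signals they would rank 4 and 17 in the list. In the same way 136 peaks were left out of the larger list, 71 of replicate 1's and 125 of replicate 2's. The rule by which these peaks were left out is not given in the sources used here.

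Replicate 1's thresholded list held 15 peaks (0.539% of its peaks) outside the main chromosomes, all on unplaced contigs of the X chromosome, where replicate 2's list held 0. No biological explanation was tested for any of these sets.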

How the results depend on the processing

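The IDR threshold of 0.001, that of 0.05 (taken from the ranked list, so that no region was excluded either), the removal of overlapping peaks, the shuffled windows, the stratified tests and the counts at stc in other lists were chosen after the data were examined. The replicate overlap, the promoter share of summits, its excess over failed peaks, the excess of head-to-head genes, the deficit on X and the excess of cytoplasmic ribosomal protein genes kept their direction and their side of the threshold in every alternative run. No alternative counted each head-to-head pair a single time, so these runs do not test the double count of peaks between such genes. The replicate overlap ran from 50.3% to 76.3% of replicate 1 peaks and from 36.6% to 55.9% of replicate 2 peaks. Chromosomes called numbered 4 in the larger list (X and 4 lower, 2L and 3L higher), 1 at an IDR of 0.001, 1 without overlapping peaks and 1 to 3 without each replicate. Lists bound more often numbered 1 at an IDR of 0.001 and 1 to 4 without each replicate. Stratified by TSS number and head-to-head status, 4 lists were called in either direction, by a normal approximation that is uncertain for lists with few bound genes. The axon guidance odds ratio was 2.39 at an IDR of 0.001 and 1.53 to 5.14 without each replicate. The signal difference was 0.0103 in the larger list, -0.0366 at 100 bp and -0.00315 to 0.0923 without each replicate. Motifs called at summits numbered 13 with 100 bp on each side, and at promoters 5 at an IDR of 0.001, where fewer peaks (2020) remain. Against shuffled windows 363 words were called, 176 higher and 187 lower. Peaks near stc numbered 2 in the larger list, 3 at an IDR of 0.05 with no region excluded and 0 to 1 without each replicate. The tRNA odds ratio reversed to 1.66 without replicate 1. In the larger list it was 1.02, where no difference was called (Fisher's exact test, adjusted p = 0.994). Without replicate 2 the tRNA odds ratio was 0.0967, the direction of the joint list. A histone odds ratio of 1.82 with the ranked background (Fisher's exact test, adjusted p = 1) was no reversal. No histone gene was bound (0 of 111), and the value comes from the correction for an empty cell. Against shuffled windows the CACGTG E-box difference was 0.0261 percentage points and was not called. Reversed there were the differences, in percentage points, of the CAGCTG E-box (1.36), GAGA (1.10), the TATA box (-1.51), TCT (1.80) and CTCF (0.992). The cause was not tested, except that shuffling keeps the A and T content of the summit. Of the 89 genes named by the rule, 88 were bound in the larger list, 79 without replicate 1, 75 without replicate 2, 73 at an IDR of 0.001 and 33 at 100 bp. The IDR of 0.01 planned as a stricter threshold removed no peak and says nothing about stability. No paired analysis was possible because there is 1 group. Read depth is unknown, so what it limits could not be measured.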

Other observations

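The test of other housekeeping promoters, the word CAGTGC and the genes named in the next paragraph were chosen after the values were seen.

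Several long genes held many summits. The gene body of kirre, a cell adhesion gene of muscle founder cells, held 19 summits over 394.1 kb (11.3 at the mean density of the genome). That of sbb held 15 over 79.1 kb (2.26), CHES-1-like 14 over 27.1 kb (0.774), shn, a zinc finger factor of Dpp signalling, 12 over 58.3 kb (1.67), and Raf, the MAP kinase pathway kinase, 11 over 48.4 kb (1.39). The gene body of ftz-f1 held 10 (1.45) and that of EcR, the ecdysone receptor, 8 (2.32). No test was run on these counts.

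Replicate 2 had more tRNA genes bound than replicate 1 (41 and 2 of 290), and more axon guidance genes (19 and 6 of 50). The difference between the replicates was not tested.

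GC content fell at the summits. The dip was -10.6 percentage points (SE 0.281) at peaks away from promoters, so the composition of promoters is not its whole cause. Ranked peaks that failed the threshold went the other way, with GC 2.72 percentage points higher at the summit. Their dip was -28.1% of that of the kept peaks, so the dip was not common to all called peaks. Failed peaks lay in coding exons far more often than kept peaks did, and the comparison was not matched by class. It therefore cannot decide whether a bias at the kept peaks underlies the dip. A preference for DNA rich in A and T, of this protein or of open chromatin in general, may underlie the dip and stays open, since no control experiment was analysed here.

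Cytoplasmic ribosomal protein promoters had an odds ratio of 14.4 (9.45 to 21.9). Proteasome and oxidative phosphorylation promoters together had an odds ratio of 0.480 (95% confidence interval 0.224 to 1.03), so these constitutive promoters did not share the excess, but they are the general-function lists with the lowest odds ratios. Stratified by the number of TSSs and head-to-head status, the ribosomal protein odds ratio was 12.4 (7.78 to 19.9). The other general-function lists ran, in the same strata, from ubiquitin genes (0.711, 0.257 to 1.97) to heat shock genes and chaperones (2.03, 0.709 to 5.79), which argues against an excess of this size at general-function promoters and leaves a smaller one open. High transcription of these genes in the embryo may also give peaks in an immunoprecipitation, which was not tested, and no biological explanation was tested.

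Of the 3831 peaks, 77 had a signal under 10 and still passed an IDR of 0.01. Of these, 73 (94.8%, exact 95% confidence interval 87.2 to 98.6) overlapped a ranked peak with a signal at least 10 times higher. This is consistent with shoulders of strong peaks that were matched to the strong peak when the lists were compared.

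Other tests gave these values. The word CAGTGC, taken from 2080 words, was present at 220 summits (5.74%), in 4.28% of windows 300 bp away (exact McNemar test, adjusted p = 0.00762) and in 3.05% of shuffled windows (adjusted p = 5.81e-07). The related CAGTGG was more frequent at summits (4.65%) than in shuffled windows (1.67%, exact McNemar test, adjusted p = 1.23e-11) and less frequent than in windows 300 bp away (5.98%, adjusted p = 0.0198). For CAGTGC, 0 of the 220 lay in an annotated transposable element, against 7 of the other 3611 summits (0.194%). With so few summits in such elements, the count of 0 decides nothing about the word. The odds ratio of CAGTGC at non-promoter against promoter summits was 0.976 (0.732 to 1.30). The axon guidance odds ratio stratified by the number of TSSs and head-to-head status was 3.52 (1.82 to 6.81). Of 2451 peaks called in 1 replicate alone, 79.2% (77.5 to 80.8) overlapped a ranked peak of the other replicate. The ranked lists are long (104070 peaks in replicate 1 and 94143 in replicate 2). The overlap that random placement would give was not computed for them.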
